A study of Xenopus laevis with 9 samples.

How the data were processed

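Gene expression was measured in the liver of Xenopus laevis, the African clawed frog, at 3 stages of metamorphosis given in the Nieuwkoop and Faber (NF) system: NF52, NF62 and NF66. Each stage had 3 samples, and per the labels' protocols each sample pooled the tissue of 5 to 10 animals. Each sample was hybridised to 1 Agilent 2-colour array of 60-base probes. Per the labels, liver RNA carried the green dye Cy3 and a universal Xenopus reference RNA carried the red dye Cy5 on all 9 arrays, so no dye swap was available and a dye effect common to all arrays cancels only in differences between stages. The labels name thyroid hormone as an agent for all 9 samples, with no dose and no untreated samples, and the series design text gives the hormone level as equal across samples. Neither says whether hormone was given to the animals or names their own, so the differences between stages are not taken here as those of untreated metamorphosis. Stage was the only factor that could be compared. The samples of a stage are separate pools, and p-values measure the spread between pools.

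The deposited scanner files hold spot intensity values on a linear scale, made with Agilent Feature Extraction, version A.7.5.1 per the file headers, together with flags for outliers, saturation and signal well above background. The same files hold the processed signals and their log10 ratio of Cy5 over Cy3, after subtraction of a local background and dye normalization per the file headers. The series' value table, which the authors deposited with its scale unstated, held log10 values for 21808 spots. Set against the scanner files, 99.99% of its values lay within 0.001 of the mean log10 reference signal over the arrays minus the log10 ratio of the array, so that a difference between 2 arrays in the table equals the difference of their log10 liver over reference ratios. Its column medians lay between 2.79 and 2.80. The direction and scale of the table were settled by this comparison, and it was used as an alternative.

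From the deposited intensity values, the mean signal of each spot was corrected with its median local background by normexp with an offset of 50, over all 22444 spots, and normalized within each array by loess, with the 314 negative and 322 positive control spots and the outlier spots at weight 0. The sign was turned so that each value is the log2 ratio of liver over reference. Outlier spots (9 to 73 of the gene spots per array) were left out and saturated spots were kept. The spots of 1 probe were averaged, which left 21807 probes. No scaling between arrays was applied. A filter fixed beforehand kept probes whose Cy3 signal was well above background on all arrays of at least 1 stage. The flag was set for 100% of gene spots on every array, so it removed no probe.

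The precision is limited by the 3 arrays per stage. Median net Cy3 signal, after subtraction of the local background, ranged from 246 to 297 over gene spots and from 199 to 227 over negative control spots, which carry no matching sequence. Between 51.3% and 70.9% of the probes on an array exceeded the 95th percentile of its negative control spots in Cy3. If part of the signal of dim spots is common to all spots, the fitted changes of dim probes are compressed, by an amount that was not settled.

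Stages were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in 1 fit to all 9 arrays that shared the estimate of the spread, with 6 residual and 3.48 prior degrees of freedom. The comparisons were NF62 versus NF52, NF66 versus NF62, NF66 versus NF52, NF62 versus the mean of NF52 and NF66, and a moderated F test over the 3 stages. The p-values were adjusted by the Benjamini-Hochberg method over the 21807 probes within each comparison, and probes with an adjusted p below 0.05 are called changed, as rises or falls. The same steps were tested on simulated data for NF62 versus NF52, with all 21807 probes and 50 changed probes per fold size. The changed probes were drawn from bright ones. Their net Cy3 signal, after subtraction of the median negative control signal, still exceeded that median. Recovery among dimmer probes was not simulated. The fit recovered 72% of the probes changed 1.5-fold, with a median fitted log2 change of 0.55 for a true 0.58. It recovered 100% of those changed 2-fold, with 0.89 for a true 1, and 100% of those changed 4-fold. It recovered 98% of those lowered to 0.5-fold. Among 21607 unchanged probes it made 2 false calls. The simulation gave all arrays the same NF52 profile and every probe the same spread, with no outlier spots and no array that stood apart. Recovery and false calls in the real data may therefore be less favourable.

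The scanner files name probes by GenBank accession and pair none with a gene symbol. None of the accessions matched the RefSeq gene table of the assembly Xenopus_laevis_v10.1 used here (0 matches among 44456 genes). The 29 gene lists fixed beforehand, the tests over these lists and the part of the naming rule that needs symbols could therefore not be used. In their place, the naming rule's ranking was applied to probe identifiers: for each pair of stages, the 2 largest rises and the 2 largest falls among changed probes whose 3 arrays of 1 stage all lay above the 3 of the other. Each is given with its 60-base sequence, and its gene was left unnamed.

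Overlaps between comparisons that share arrays were set beside 20 simulated data sets with no change between stages and beside the overlap of independent lists. The shares of change kept at NF66 were set beside 20 simulated data sets in which every called change at NF62 was undone at NF66, with the fitted spread of each probe, a simulation added after the shares were seen. Probe sequences were compared with each other by blastn 2.17.0, and pairs on the same strand with at least 80% identity over at least 40 bases were called similar. The alternatives covered the background correction, the normalization, the value table, the Cy3 channel alone with quantile normalization between arrays, filters on dim probes, the replicate number as a block, the variance model, the arrays in the fit, a minimum change of 2-fold and leaving out each array in turn. Alternatives with a background taken from the negative control spots and with a filter on their 95th percentile were added after the data were seen. The comparisons, their tests and the other alternatives were fixed before the data were examined. Each array lay on a slide of its own, so slide could not be fitted as a block.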

Results

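The liver of the frog Xenopus laevis was profiled at 3 points of metamorphosis, the change from tadpole to frog that thyroid hormone controls. In normal development NF52 is a tadpole stage before metamorphosis, NF62 lies at its climax, and NF66 is the young frog at its end. The labels name thyroid hormone as an agent for all samples without saying whether it was given, so stage names are used here as labels of the samples. The series title sets the arrays in a study of how thyroid hormone controls the remodelling of the pancreas and the liver, and the comparisons ask how the liver transcriptome differed between these stages. Each stage had 3 arrays, 9 in all, each with a separate pool of animals in Cy3 against a universal reference in Cy5. Values are log2 ratios of liver over reference for 21807 probes. The median Cy3 signal of the gene spots was similar on the 9 arrays, from 644.5 to 693.5 intensity units over a local background of 391 to 400. Between 11 and 32 gene spots per array were saturated in Cy3. No probe could be paired with a gene name, so individual results are given by probe.

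Arrays of a stage correlated more closely with each other than with arrays of another stage, except NF66 replicate 3, which correlated as closely with an NF62 array as with NF66 replicate 1. Across probes, which are not independent replicates, Pearson's r was 0.970 to 0.975 among the NF52 arrays, 0.956 to 0.964 among the NF62 arrays and 0.903 to 0.966 among the NF66 arrays. Between stages it ranged from 0.764 to 0.903, the highest value being that of NF66 replicate 3 with NF62 replicate 1. The median SD of a probe within a stage was 0.07 at NF52, 0.08 at NF62 and 0.09 at NF66 on the log2 scale (n = 3 each). The first principal component held 47.2% of the variance and the second 31.6%. The first placed NF52 apart from the later stages, and the second placed NF62 apart from NF66. NF66 replicate 3 lay nearer to the NF62 arrays than NF66 replicates 1 and 2 did.

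**Figure D1:**
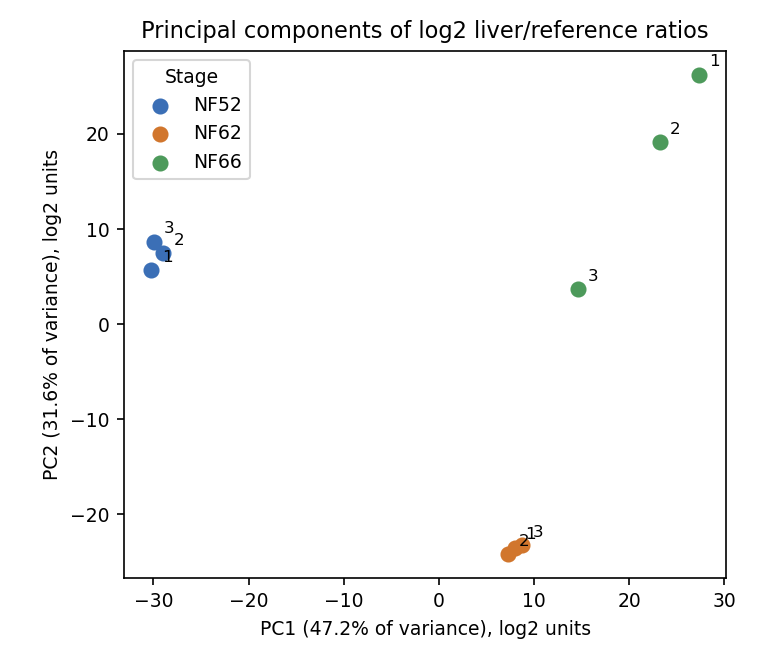
Principal components 1 and 2 of the log2 liver over reference ratios of the 9 arrays; each point is 1 array, coloured by stage and numbered by replicate, and both axes are in log2 units. The NF52 arrays sit between -30.2 and -29.0 on the first component, the NF62 arrays between -24.1 and -23.2 on the second, and NF66 replicate 3 at 3.71 on the second against 26.2 and 19.1 for replicates 1 and 2.

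The comparison of NF62 with NF52 sets samples labelled with the climax stage against those labelled with the early tadpole stage. In all, 2002 probes changed, 9.18% of those tested, of which 995 rose and 1007 fell. Changes of at least 2-fold were seen in 194 rises and 203 falls, and changes of at least 4-fold in 54 rises and 37 falls. The median absolute log2 change of the changed probes was 0.56. The rises reached higher than the falls went low. Probe BX852411_840 (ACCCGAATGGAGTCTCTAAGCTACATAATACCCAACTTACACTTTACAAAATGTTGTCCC) rose from a log2 ratio of -4.66 ± 0.11 (SD, n = 3) at NF52 to 2.78 ± 0.08 at NF62, a log2 change of 7.44 ± 0.12 (SE; limma adjusted p = 1.06e-09). Its NF52 level lay near the background: on 2 of the 3 NF52 arrays its Cy3 signal exceeded the 95th percentile of the negative control spots. The size of its change therefore depended on the background correction, from 5.80 without any to 8.01 with the background taken from the negative control spots. Probe BF611948_500 (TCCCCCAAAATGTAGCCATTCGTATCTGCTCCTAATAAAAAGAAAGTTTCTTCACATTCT) rose by 7.13 ± 0.14 (SE; limma adjusted p = 2.26e-09), from -4.96 ± 0.08 to 2.17 ± 0.14, and the change was 6.50 without background correction. It was saturated on 2 of the 3 NF62 arrays, where the scanner value is only a lower limit of the signal. That does not make 7.13 a lower limit of the change, as its size depends on the processing. The quantile-normalized Cy3 channel alone gave 6.62. In the other direction, BC056841_1488 (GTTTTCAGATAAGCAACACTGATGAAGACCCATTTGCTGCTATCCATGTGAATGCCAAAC) went from 2.06 ± 0.41 to -2.83 ± 0.37, a change of -4.89 ± 0.30 (SE; limma adjusted p = 6.54e-06), or -4.25 without background correction. BC061682_1180 (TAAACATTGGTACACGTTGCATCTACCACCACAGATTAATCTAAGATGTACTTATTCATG) went from 4.58 ± 0.07 to -0.01 ± 0.22, a change of -4.58 ± 0.12 (SE; limma adjusted p = 1.50e-08). It was saturated on 1 of the 3 NF52 arrays, where the value is a lower limit. For each of these 4 probes the 3 arrays of 1 stage all lay above the 3 of the other. That was part of the rule that chose them, so it is no separate support. Over all probes such a separation held for 29.4%, where chance gives 10%. Among the changed probes it held for 99.9%, which follows largely from the call itself.

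The balance of rises and falls from NF52 to NF62 depended on the dye normalization. With each array centred on its median in place of loess, 1354 probes changed, of which 423 rose and 931 fell. The Cy3 channel alone, with quantile normalization between arrays in place of loess, tilted the other way, with 882 rises and 641 falls. Without NF52 replicate 3, the count of changed probes was 1298. A change of at least 2-fold as well as the threshold left 397 probes. Without background correction, 88 rises and 95 falls reached 2-fold.

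**Figure D2:**
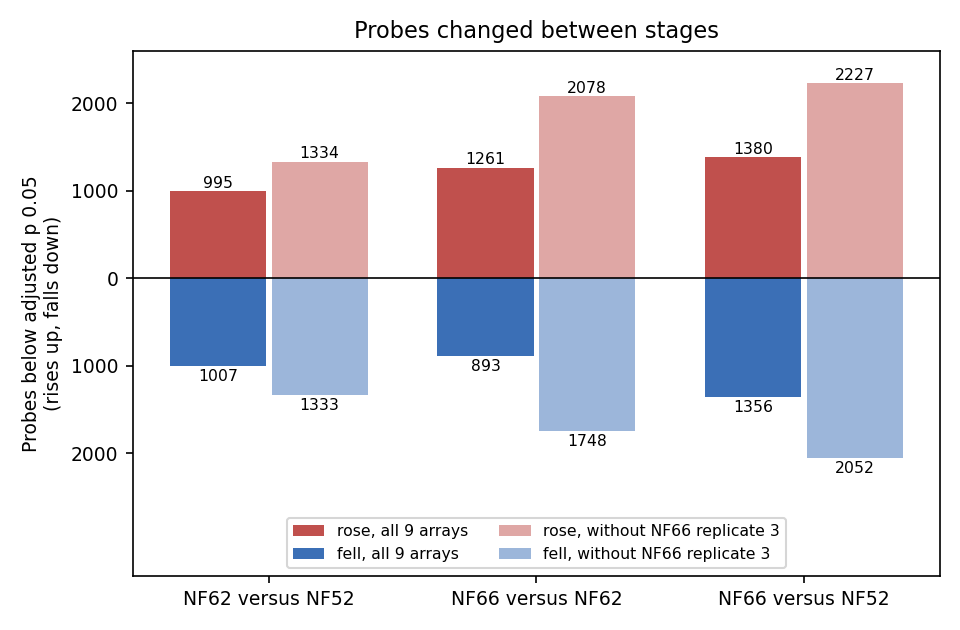
Counts of probes below an adjusted p of 0.05 in the 3 comparisons between stages, with rises drawn above 0 and falls below it; darker bars are from all 9 arrays and lighter bars from the 8 arrays without NF66 replicate 3. Without that array the rises from NF62 to NF66 go from 1261 to 2078 and the falls from 893 to 1748.

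The comparison of NF66 with NF62 sets the samples of the last stage against those of the climax stage. Here 2154 probes changed, 9.88% of those tested, with 1261 rises and 893 falls. Rises prevailed among the larger changes: 242 probes rose and 81 fell by at least 2-fold, and 37 rose and 5 fell by at least 4-fold. The median absolute log2 change of the changed probes was 0.52. Probe BX846062_554 (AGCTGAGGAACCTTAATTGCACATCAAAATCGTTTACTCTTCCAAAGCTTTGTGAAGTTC) was at 0.22 ± 0.59 (SD, n = 3) at NF52 and 0.17 ± 0.27 at NF62 and rose to 4.97 ± 0.29 at NF66, a change of 4.80 ± 0.27 over NF62 (SE; limma adjusted p = 1.48e-05). CD301429_837 (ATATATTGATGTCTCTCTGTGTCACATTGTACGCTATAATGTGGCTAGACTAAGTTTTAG) dipped at the climax, with 2.35 ± 0.62 at NF52, -0.998 ± 0.08 at NF62 and 3.47 ± 0.17 at NF66, and its rise over NF62 was 4.46 ± 0.25 (SE; limma adjusted p = 1.43e-05). BC053782_1123 (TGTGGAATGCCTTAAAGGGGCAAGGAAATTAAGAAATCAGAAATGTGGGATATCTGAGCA) was high at NF52 (4.16 ± 0.08) and NF62 (4.75 ± 0.21) and went to -0.01 ± 0.13 at NF66, a change of -4.76 ± 0.11 (SE; limma adjusted p = 6.29e-08). U41855_2167 (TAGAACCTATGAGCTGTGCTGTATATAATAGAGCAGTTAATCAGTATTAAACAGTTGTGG) was high at the climax alone. It stood at -2.97 ± 0.06 at NF52, 0.54 ± 0.16 at NF62 and -2.49 ± 0.18 at NF66, and its change from NF62 to NF66 was -3.03 ± 0.10 (SE; limma adjusted p = 1.34e-06). Without background correction, the change was 4.03 for BX846062_554, 3.68 for CD301429_837 and -2.19 for U41855_2167. In each of these probes the 3 NF66 arrays all lay on 1 side of the 3 NF62 arrays, as the rule that chose them requires. Over all probes such a separation held for 25.7%, where chance gives 10%.

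The count for NF66 versus NF62 depended on each array of the comparison. Without NF66 replicate 3 it was 3826 (2078 rises and 1748 falls), and without NF66 replicate 1 or 2 it was 1299 or 1085. It was 1112, 1229 and 1275 without NF62 replicates 1, 2 and 3, and 1050 in a fit to the arrays of the 2 stages alone. Median centring gave 1006 rises and 330 falls, and the quantile-normalized Cy3 channel alone gave 677 rises and 803 falls. Among changes of at least 2-fold, rises outnumbered falls under every alternative tried for this comparison, including the quantile-normalized Cy3 channel alone (184 rises and 77 falls) and no background correction (65 rises and 33 falls). Without NF66 replicate 3, 374 rises and 119 falls reached 2-fold.

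Between the first and the last stage sampled, NF52 and NF66, 2736 probes changed, 12.5% of those tested, with 1380 rises and 1356 falls. Of these, 276 rose and 167 fell by at least 2-fold, and 64 rose and 21 fell by at least 4-fold. Without background correction, 106 rises and 71 falls reached 2-fold. The probes with the largest rises from NF52 to NF62 also had the largest rises here: BX852411_840 reached 3.04 ± 0.28 (SD, n = 3) at NF66, a change of 7.71 ± 0.12 over NF52 (SE; limma adjusted p = 1.74e-09). With its NF52 level near the background, this change ranged from 6.04 without background correction to 8.29 with the background from the negative control spots. BF611948_500 was saturated on all 3 NF66 arrays and was at least 98.6-fold higher than at NF52 (limma adjusted p = 2.65e-09). This bound sets the mean log2 Cy3 signals against each other after loess and Aquantile normalization, with saturated spots at their value, and is open to dye bias that differs between arrays, as no dyes were swapped. It holds for this background correction and normalization: the fitted log2 change was 6.44 without background correction, a smaller fold. BC053782_1123 was lower than at NF52 by a log2 change of -4.17 ± 0.11 (SE; limma adjusted p = 1.68e-08). BC054271_1668 (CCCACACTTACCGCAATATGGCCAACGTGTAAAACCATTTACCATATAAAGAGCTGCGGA) was at 0.24 ± 0.50 at NF52, -3.41 ± 0.11 at NF62 and -3.93 ± 0.24 at NF66, a change of -4.17 ± 0.22 over NF52 (SE; limma adjusted p = 2.33e-06). Its net Cy3 signal was 323 at NF62 and 267 at NF66, where the array medians of the negative control spots ranged from 199 to 227. On all 3 arrays of each stage it exceeded the negative control percentile applied to BX852411_840. A fall was present at NF62, but its share of the whole cannot be read, as both later levels lay near the background. Its change was -2.52 without background correction. Without NF66 replicate 3, 4279 probes changed (2227 rises and 2052 falls). The count was 1572, 1570 and 1674 without NF52 replicates 1, 2 and 3, and 1629 without NF66 replicate 2. Median centring gave 877 rises and 1125 falls, and the quantile-normalized Cy3 channel alone 823 rises and 876 falls, 1699 in all.

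**Figure D3:**
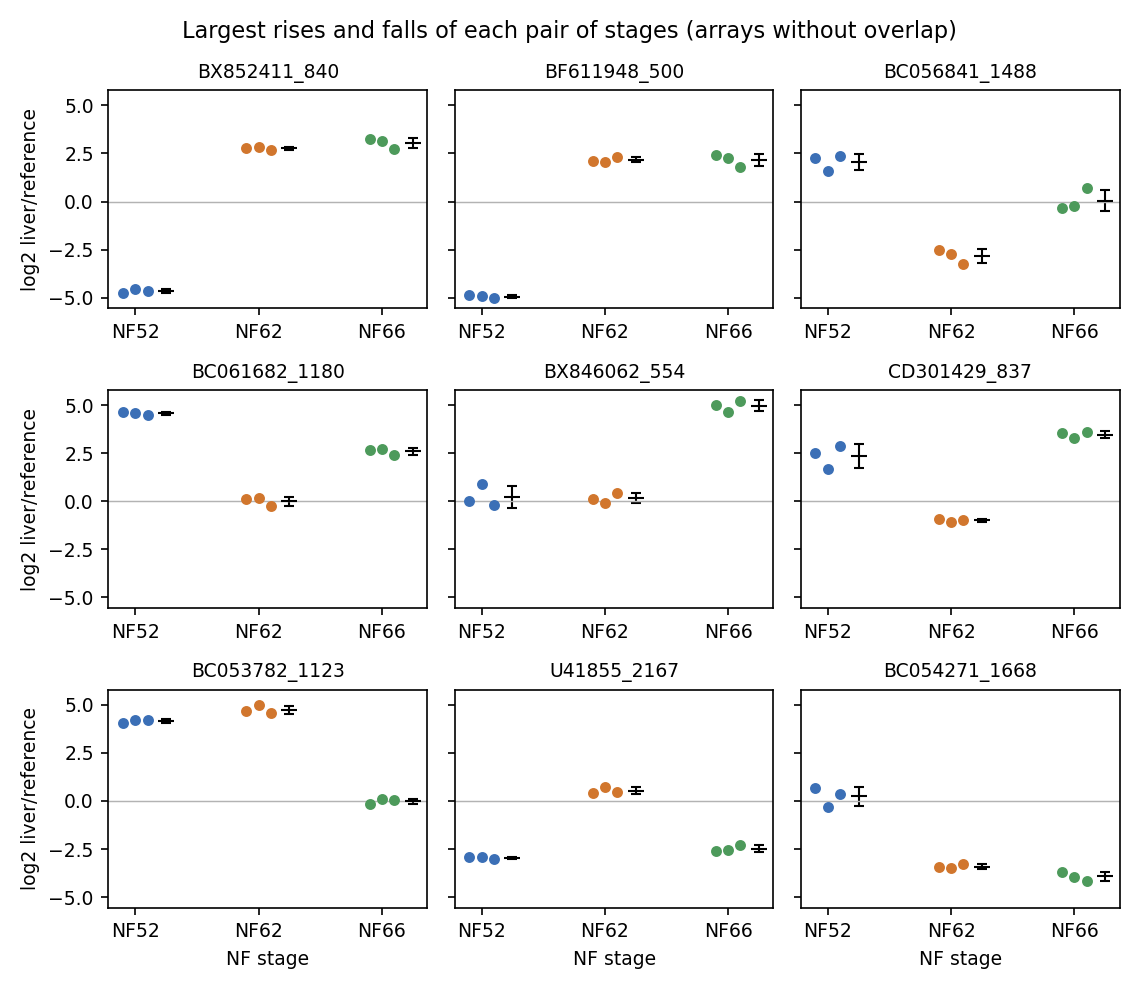
Log2 liver over reference ratios of 9 probes, 1 panel per probe: for each pair of stages the 2 largest rises and the 2 largest falls among changed probes whose arrays did not overlap, some of them shared between pairs; coloured points are the 3 arrays of each stage, and the black bar with its error bar is the mean and SD of the stage (n = 3). BX852411_840 rises from -4.66 at NF52 to 2.78 at NF62 and stays at 3.04 at NF66, while U41855_2167 is at 0.54 at NF62 and below -2 at the other stages.

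The climax was also set against the mean of the stages on either side of it. For NF62 versus the mean of NF52 and NF66, 915 probes were higher and 949 lower at the climax than that mean, 1864 in all. By at least 2-fold, 91 were higher and 124 lower. The contrast can also call a probe that changed at 1 step alone and kept its new level. These are therefore not counts of probes highest or lowest at NF62. The moderated F test found a difference among the 3 stages for 3629 probes, 16.6% of those tested. Without NF66 replicate 3, the climax contrast called 3420 probes (1548 higher and 1872 lower), and without NF62 replicate 1 or 3 it called 1140 or 1186. Median centring gave 345 higher and 896 lower, and the quantile-normalized Cy3 channel alone 928 higher and 579 lower.

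Probes that differed between NF52 and NF62 took several courses between NF62 and NF66. Of the 995 probes that rose from NF52 to NF62, 372 fell again from NF62 to NF66, 38 rose further, and 585 had no call at the second step. Of the 1007 that fell at the first step, 278 rose again, 55 fell further and 674 had no call. A further 945 probes rose and 466 fell at the second step with no call at the first. Of the 372 that rose and then fell, 294 (79.0%) had no call between NF66 and NF52, and of the 278 that fell and then rose, 180 (64.7%) had none. A missing call does not show that the level had returned.

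These courses depended on NF66 replicate 3. Without it, 695 probes rose and then fell, 74 rose at both steps, 412 fell and then rose, and 147 fell at both steps. A further 1592 rose and 906 fell at the second step with no call at the first. Of the 695 that rose and then fell, 483 (69.5%) had no call between NF66 and NF52, and of the 412 that fell and then rose, 197 (47.8%) had none. Of these 412, 132 were called higher at NF66 than at NF52, against 31 of the 278 with all arrays.

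The changes of at least 2-fold at the first step were mostly still seen at NF66. Of the 194 such rises, 158 were called higher at NF66 than at NF52, 36 had no call and 0 were called lower. Of the 203 such falls, 160 were called lower, 38 had no call and 5 were called higher. At NF66 the rises kept a median of 82.8% of their log2 change (quartiles 52.4% and 103%), and the falls 70.2% (quartiles 41.3% and 96.2%). Both differences use the same NF52 arrays. In 20 simulated data sets with the called changes at NF62 and a full return at NF66, the median share kept was 0.75% for rises and 0.54% for falls, at most 2.06% and 2.61%, and 0 of either were called at NF66. From NF62 to NF66, 72 of the 194 rises and 92 of the 203 falls moved back past the threshold, a difference that did not pass Fisher's exact test (two-sided p = 0.104, over probes, which are not independent). Without NF66 replicate 3, 102 of 195 rises and 96 of 203 falls moved back, and the median shares kept were 76.3% and 74.5%.

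**Figure D4:**
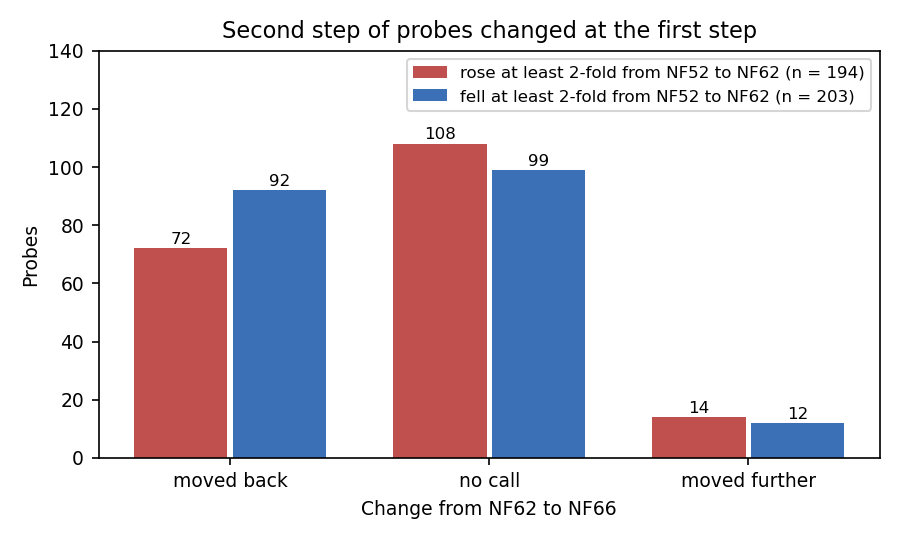
Numbers of probes, among those changed at least 2-fold from NF52 to NF62, that moved back, had no call or moved further from NF62 to NF66; bars start at 0, red bars are the 194 rises and blue bars the 203 falls of the first step. Of the rises 72 moved back and 14 moved further, and of the falls 92 moved back and 12 moved further.

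Comparisons with a stage in common share its arrays. NF62 versus NF52 and NF66 versus NF52 had 469 rises and 613 falls in common, where independent lists of the same sizes give 63.0 and 62.6. They disagreed in direction for 19 and 31 probes. NF62 versus NF52 and NF66 versus NF62 had 38 rises and 55 falls in common, against 57.5 and 41.2 from independent lists, while 372 probes rose and then fell, against 40.7, and 278 fell and then rose, against 58.2. In 20 simulated data sets with no change between stages, 0 probes were called in both comparisons of any pair; with no change there are almost no calls to overlap, so this value does not measure what the shared arrays add among changed probes. Pearson's r of the log2 changes across probes was 0.65 between NF62 versus NF52 and NF66 versus NF52, where simulated unchanged stages gave 0.50 from the shared NF52 arrays, and -0.35 between the 2 successive steps, where they gave -0.50. The covariance was 0.0767 against a simulated 0.0046 in the first case and -0.0339 against -0.0046 in the second. Part of each overlap may come from the shared arrays. That part of the counts was not separated, since the 3 arrays of a stage cannot be divided into sets of at least 2.

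NF66 replicate 3 stood apart from the other NF66 arrays. Over the 3808 probes that differed between NF62 and NF66 replicates 1 and 2 and were measured on all arrays involved, its median position was 0.61 of the way from NF66 replicates 1 and 2 to NF62 (quartiles 0.34 and 0.85). The same measure was -0.28 for replicate 1 and 0.01 for replicate 2, each against the other NF66 arrays. The shift was uneven. Among the 68 probes that rose by at least 4-fold from NF62 to replicates 1 and 2, 46 lay more than 0.5 of the way back to NF62 in replicate 3 on the linear scale, and 16 lay less than 0.1 of the way back. The probes named above kept their direction and stayed past the threshold without this array.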

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

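The tests on NF66 replicate 3 and on the negative control spots were chosen after the result was seen. Spots outside the main measurement carried signal: the negative control spots, which match no transcript, had a median net Cy3 signal of 76.2% of that of the gene spots (median of the 9 arrays, range 72.4% to 83.5%), against 25.2% in Cy5. Such a signal, if common to all spots, compresses the ratios of dim probes. With the background taken from the negative control spots, the absolute log2 changes of the probes called between NF52 and NF62 were larger by a median factor of 1.08 (quartiles 1.01 and 1.17), which lay between the bounds set for a clear effect and for none. Of these called probes, 1761 lay among the brighter and 241 among the dimmer, split at the median intensity. The factor therefore says little about dim probes. The size of the compression stays open, and no biological explanation was tested. Counts of changed probes under this background were 1958, 2167 and 2980 for NF62 versus NF52, NF66 versus NF62 and NF66 versus NF52.

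NF66 replicate 3 lay between the NF62 arrays and the other NF66 arrays. An NF62 pool under a wrong label is argued against by its highest correlation with an NF62 array, 0.903 across probes, below the lowest among the NF62 arrays, 0.956. The reference channel or dye normalization is argued against by the quantile-normalized Cy3 channel alone, in which the median position was 0.59. Noise of that array was not settled. Its deviation from replicate 1 and the difference of NF62 from replicate 2, which share no array, correlated across probes at 0.53. Replicate 1 itself lay away from NF62. On the linear scale from replicate 2 to NF62, its median was -0.21 over probes at least 2-fold lower at NF62 and -0.02 over those at least 2-fold higher. Its own offset can give such a correlation, so the test cannot decide. NF62 RNA mixed into the pool stays open. It needs 1 mixing share for every probe. The median share was 0.28 over the 119 probes at least 2-fold higher at NF62. It was 0.70 over the 372 at least 2-fold lower, a difference of 0.42. Against axes that hold replicate 3, the difference was 0.34 for replicate 1 and 0.10 for replicate 2, both in the opposite direction. With axis and probes from replicate 1 alone, it was 0.33 for replicate 3 and 0.098 for replicate 2. From replicate 2 alone, it was 0.42 for replicate 3 and -0.20 for replicate 1. Replicates 1 and 2 thus also gave a difference, smaller in size than that of replicate 3. The test does not separate a mixture from the spread between pools. A pool of animals that differed in stage, physiology or dissected tissue also stays open, as untested.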

How the results depend on the processing

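The background from negative control spots and the filter on their 95th percentile were chosen after the data were seen. The 12 changes of single probes kept their direction and an adjusted p below 0.05 under all 288 alternatives run for them (limma; highest adjusted p 0.000289). Their sizes did not all hold: 9 of the 12 moved by over 1.5 times in fold under some alternative, each with no background correction, which gave smaller changes. BC054271_1668 went to -2.52 from -4.17, and BX852411_840 from NF52 to NF62 ranged from 5.80 to 8.01. Of the counts, median centring moved NF66 versus NF62 to 1336 and the climax contrast to 1241, and the Cy3 channel alone with quantile normalization, which changes both the channel and the normalization, moved NF66 versus NF52 to 1699; the cause was not tested. A fit to the arrays of the 2 stages alone gave 1050 for NF66 versus NF62, while it gave 2738 for NF62 versus NF52 and 2041 for NF66 versus NF52. The log2 changes are the same in this fit and the main one, so only the estimate of the spread and its degrees of freedom differ. Without NF66 replicate 3, NF62 versus NF52 gave 2667, though no NF66 array enters its difference. The parts of spread and degrees of freedom were not tested apart. A minimum change of 2-fold, a stricter rule by construction, left 397 for NF62 versus NF52, 323 for NF66 versus NF62, 443 for NF66 versus NF52, 215 for the climax contrast and 735 for the F test. Leaving out each array in turn gave 1298 to 2667 for NF62 versus NF52, 1085 to 3826 for NF66 versus NF62, 1570 to 4279 for NF66 versus NF52, 1140 to 3420 for the climax contrast and 2449 to 5319 for the F test. Every highest value came without NF66 replicate 3. The replicate block gave 1782, 1874, 2339, 1674 and 3139 in the same order. No link between same-numbered arrays was seen: their deviations correlated between -0.10 and 0.04, and 1 of the 9 arrays correlated best with its own number. Differently numbered arrays of different stages ranged from -0.08 to 0.105. This does not show that same-numbered arrays share nothing. Aquantile normalization and no filter on dim probes changed no value, the first because it leaves ratios as they are and the second because the filter removed nothing. Gene-list tests (camera, fry, probe means) were not run, as no probe had a gene symbol, and slide as a block was not run, as each slide held 1 array. Signal over background limits dim probes most: on an array 51.3% to 70.9% of probes exceeded the negative controls in Cy3.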

Other observations

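The test on the dye bias was chosen after the result was seen, and those on similar sequences and on other splits of the arrays before. The largest rises held several related sequences. The 54 probes that rose at least 4-fold from NF52 to NF62 fell into 44 families of similar sequence, and the 64 that did so from NF52 to NF66 into 56, while the 37 and 21 falls of that size held no similar pair. BX852411_840 had 2 similar probes on the array and BF611948_500 had 1. Over all 231 pairs of similar probes, the log2 changes from NF52 to NF62 correlated with a Pearson's r of 0.92 across pairs (Spearman's rho 0.68), where 1000 random pairings reached at most 0.35. The hypothesis that similar probes report the same or related transcripts may account for this. Both probes of a pair were called in the same direction in 39 pairs and in opposite directions in 0. From NF52 to NF66 the pair was called in opposite directions in 2 of the 231. In one, BC044087_2026 changed by 0.69 and BC047977_2035 by -0.60, with 85% identity over 40 bases. In the other, BC054166_828 changed by 0.44 and BC044039_1370 by -0.46, with 80% identity over 60 bases. These 4 probes were chosen after their values were seen.

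The balance of rises and falls was also counted among dimmer and brighter probes, with no test of the difference. Among the dimmer probes, split at the median intensity over all arrays, 55 of the 259 calls of the climax contrast were higher at NF62 (21.2%), against 860 of 1605 (53.6%) among the brighter. For NF66 versus NF62, 318 of 404 calls of dimmer probes were rises (78.7%), against 943 of 1750 (53.9%). The shares of rises were 32.0% and 52.1% for NF62 versus NF52, and closer, at 55.0% and 49.3%, for NF66 versus NF52. Under median centring, where falls outnumbered rises from NF52 to NF62, a dye bias that depends on intensity was predicted to lower the share of rises among dimmer probes. The share was higher there by 7.47 percentage points, so the prediction was not met. The test did not reach the bound set against it either. The prediction covered dimmer probes only, so the test cannot decide on a bias that acts on brighter ones. With median centring in place of loess, the share of rises went from 52.1% to 30.3% among brighter probes. Among dimmer probes it went from 32.0% to 37.8%. The cause of the imbalance stays open.

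The Cy5 reference, which was nominally the same RNA on all arrays, gave 6 calls for NF62 versus NF52, 2 for NF66 versus NF62 and 3 for NF66 versus NF52 when fitted alone with limma, with 1725, 1739 and 2490 probes at an unadjusted p below 0.05. Each of these 3 larger counts exceeded a share of 0.05 of the 21807 probes, which no difference would give. The few calls therefore do not show that the reference signal was the same at all stages. The cause was not tested.

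Other splits of the arrays were counted for each comparison. For the pairs of stages, with the 6 arrays of the pair alone, 10 splits are too few for a share below 5%. The real split gave 2738 probes for NF62 versus NF52, 1050 for NF66 versus NF62 and 2041 for NF66 versus NF52, was the only 1 of the 10 to give as many, and the highest of the other splits gave 0 each time. For the climax contrast, 1 of 100 splits drawn from the 9 arrays, the real one, gave as many as 1864 probes, and the highest of the others gave 1405. For the F test, 1 of 100 splits, the real one, gave as many as 3629, and the highest of the others gave 924. Both shares lay below 5%, which argues against an arbitrary grouping of the arrays as the source of the last 2 counts. With 100 splits drawn, it is not excluded. For the climax contrast, the splits also mix NF52 with NF66, so they do not test that contrast by itself.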
